A study of Homo sapiens with 4 samples.

How the data were processed

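HSC-5, an established human cutaneous squamous cell carcinoma line, was crosslinked with 1% formaldehyde for 12 min per the labels, and chromatin was immunoprecipitated with an antibody to p63. The labels give 4 samples: 2 input libraries and 2 p63 immunoprecipitates (IPs). Peak lists of IP replicates 1 and 2 were analysed here; files of the inputs were not used here. The labels do not say whether the replicates came from separate cultures, so differences between them may be technical.

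Each list was called per sample against 1 control with MACS 1.4.2, per the file headers. The headers do not say which input served as control. Per the submitters' processing notes, FastQC, Trimmomatic and Bowtie were used upstream, and the build named is hg19. Per the file headers, 1 tag was kept per position, the larger library was scaled to the smaller, the tag size was 76 bp and the p cut-off was 1e-05. The band width was 250 bp in replicate 1 and 300 bp in replicate 2. The modelled fragment lengths (d) were 82 bp and 86 bp, close to the tag size. The tag count of a peak is the authors' whole number of tags kept in it, not normalised. The deposited score is minus 10 times the log10 of the MACS p-value. The deposited fold enrichment is the ratio of the IP to the scaled local control, as the authors' caller gave it. The deposited false discovery rate is in percent and comes from exchanging IP and control, per the file headers. Peak width and summit offset are in base pairs, per the file headers. Scores and folds are the authors' values and were used to describe, rank and filter peaks within a list.

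Replicate 1 had 3 sheets with the same 4077 peaks, 22 of them with hand-written notes by the authors; 1 sheet was used. The numbering of the lists was checked against a RefSeq gene table of GRCh38.p14. Replicate 1 held 83 peaks on 45 alternate, random or unplaced contigs named as in GRCh38, and none of its peaks on chromosomes 1 to 22 and X started beyond the last protein-coding gene. Replicate 2 held 31 peaks beyond that gene on 12 chromosomes and none on such contigs. Replicate 1 was therefore read as GRCh38, although the processing notes name hg19, and replicate 2 was not placed on genes. No coordinate was converted between builds.

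Because the numberings differ, direct overlap of intervals was computed as planned but does not measure shared binding. In its place, peaks were matched by spacing. A pair of peaks, 1 per list, counted as matched when its summit offset recurred within 100 bp in at least 2 other pairs lying over 2 kb and under 10 Mb away. Offsets were limited to 5 Mb and peaks to widths under 1 kb, and each peak was used once. The chance level came from 200 rotations of replicate 2 along each chromosome by 20 to 80% of its extent. This method was devised after the lists were seen. Its tolerance, block and support were chosen from 18 combinations run on the real lists, and the setting kept gave the most pairs of the 9 combinations that required 2 supporting pairs. Its p-value does not account for that choice, and the pair count is a count under one setting. The match was tested on simulated data with 3994 peaks in list 1. It recovered 40.1% of 299 planted pairs with 2 false pairs, 80.9% of 598 with 1, 95.1% of 1201 with 1, and called none where none was planted. Simulated peaks were spread evenly at random along each chromosome, with a fixed offset per block and summit shifts within the tolerance. The real peaks are clustered, so their recovery and false pairs may differ from these values.

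Medians of matched and unmatched peaks were compared with two-sided permutation tests (100000 resamples for fold, 10000 for tags and score). Pearson's r and Spearman's rho were computed on log2 values with 100000 permuted pairings, over 3 measures with Benjamini-Hochberg adjustment. Peaks are not independent replicates, so these tests describe the libraries.

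For replicate 1, a protein-coding gene was counted as having a peak when a summit lay in its span or within 10 kb. The design fixed before the data were examined used 50 kb around the transcription start and Fisher's exact test, over peaks shared by overlap. It could not be run because the gene table has no strand and the overlap is void. The span with 10 kb was among the alternatives fixed then and became the main window after the data were examined; 50 kb either side of the span is given as an alternative. The 14 gene lists were also fixed before the data were examined. Of their genes, 1 was found under a newer symbol and 0 were missing. Each list was compared with 10000 random lists matched on gene span (10 groups) and on genes within 500 kb (5 groups), a two-sided permutation of genes within groups whose smallest p is 2.0e-04, with Benjamini-Hochberg adjustment over the 14 lists. On simulated data over 20037 genes, 20 runs without any list effect called 0 lists, and a list with 12 members given a peak was called at an adjusted p of 0.014. These runs drew fewer random lists than 10000, and 0.014 was the lowest adjusted p that 1 called list could reach. Simulated genes received peaks independently, by span alone, so the runs could not show false calls from neighbouring genes that share a peak. Neighbouring genes share peaks, so list members are not independent.

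Summit location was compared with 1000 random placements on the same chromosome up to its last gene (two-sided), which also fall in unsequenced gaps. Where gene-free spans were left out, the placements, the sequence lengths and the rate of peaks per base left them out as well. Peaks per chromosome were compared with the chromosome's share of protein-coding genes by exact binomial tests, adjusted over 1 to 22 and X. Motif tests and exon or intron assignment were planned but not run, since no genome sequence was used here.

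The genes named follow a rule fixed before the data were examined: the 10 shared peaks with the highest mean percentile rank of fold, up to 4 genes per list by rank of their peak, TP63, the 3 widest shared peaks, and the 3 highest-fold unmatched peaks of each list. Spacing-matched peaks took the place of shared peaks, and list members were ranked by their replicate 1 peak, named by the nearest gene span. Other genes named were chosen after their values were seen. Of the genes this rule and the gene density test give, 2 are not reported here. Intervals are 95% Wilson for shares, exact Clopper-Pearson for chromosome 5, and exact Poisson for tag counts; all cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.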

Results

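p63 is a transcription factor of the p53 family that maintains the basal layer of stratified epithelia. Its binding sites were mapped by ChIP-seq in HSC-5 skin carcinoma cells in 2 IP replicates, with no second condition. Replicate 1 had 22139487 IP tags, of which 12687447 were kept after duplicate removal (42.7% removed), against 28327222 control tags kept. Replicate 2 had 4089280 IP tags and 868393 kept (78.8% removed), against 13175270 control tags kept. Its kept depth was 6.84% of that of replicate 1.

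Replicate 1 held 4077 peaks, with the highest fold enrichment nearest to TMEM250 (99.67), ANAPC1 (79.96), MINK1 (74.88) and ASTN2 (70.36). The TMEM250 and ANAPC1 peaks lay 4.747 and 125.538 kb outside those genes. Replicate 2 held 2934 peaks. The median peak had 10 tags, a width of 245 bp and a fold of 13.24 in replicate 1, and 4 tags, 161 bp and a fold of 108.46 in replicate 2. In replicate 2, 1614 peaks (55.0%) held 4 tags, the lowest number in the list, while replicate 1 had a minimum of 8 tags. Peaks covered 1.22% of kept tags in replicate 1 and 2.45% in replicate 2. Folds cannot be compared between the lists, because they rest on different depths and controls.

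The question of which sites both replicates share was complicated by their numbering. At least 1 bp of overlap was seen for 21 replicate 2 peaks (0.716%), against 2.12 in 1000 random placements (one-sided permutation p = 1.0e-03, the smallest they can give). The lists use different builds, so this overlap is not a measure of shared binding. Matching by spacing gave 205 peak pairs on 17 chromosomes, which were 5.29% of 3875 replicate 1 peaks and 7.04% of 2911 replicate 2 peaks under 1 kb wide. Rotations gave a mean of 3.8 pairs and a maximum of 14 (one-sided permutation p = 0.00498, the smallest 200 rotations can give). Of the pairs, 194 had an offset of over 1 kb. The count depends on the setting chosen after the data were seen. Over 9 combinations that required 2 supporting pairs it ranged from 6 to 205, with chance means of 0 to 4.1.

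**Figure D1:**
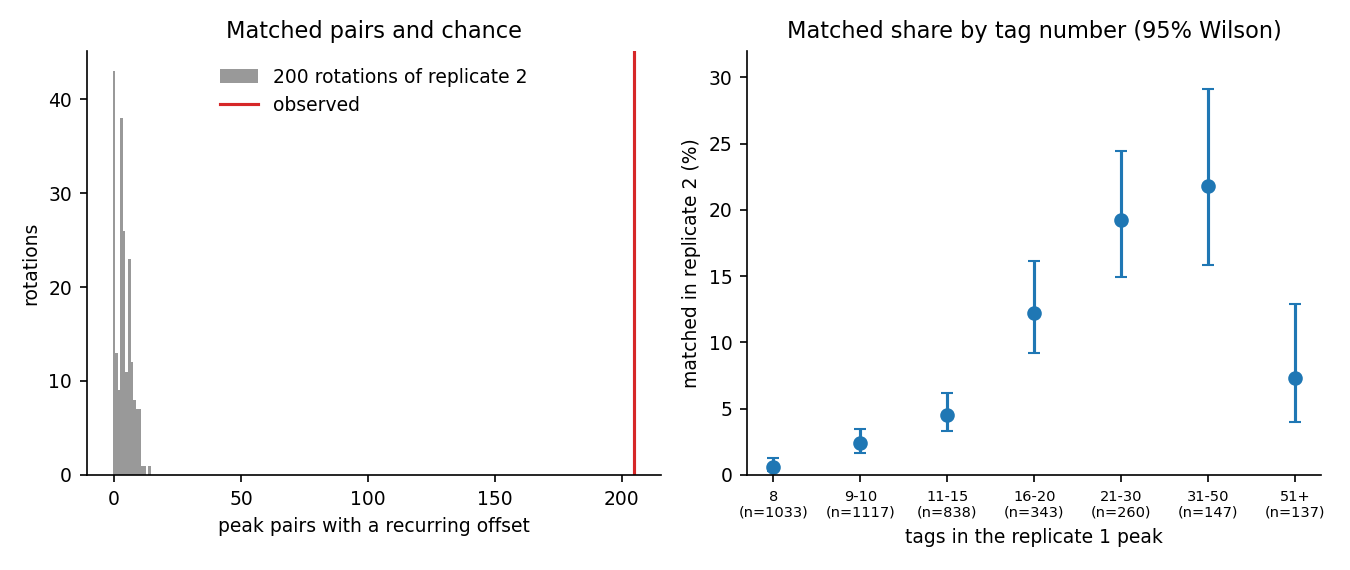
Left, number of peak pairs with a recurring offset in 200 rotations of replicate 2 (grey bars, count of rotations) and in the lists as given (red line, 205 pairs). Right, percent of replicate 1 peaks matched in replicate 2 by tag number, with 95% Wilson intervals; the share rises from 0.581% at 8 tags to 21.8% at 31 to 50 tags and is 7.30% above 50 tags.

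The matched sites that ranked highest in both lists lay near PTPN1, CRAT, FRMD8, ASTN2, DTX2, SYK, MINK1, KRT80 and SPTLC1. PTPN1 encodes a tyrosine phosphatase, and its site (GRCh38 chromosome 20, 50496655 to 50497093) lay 13.465 kb outside the gene, with 51 tags (95% interval 38.0 to 67.1) in replicate 1 and 21 in replicate 2. CRAT, a mitochondrial carnitine acetyltransferase, held a site at chromosome 9, 129102973 to 129103437, with 43 tags and 16 tags. The ASTN2 site (chromosome 9, 116686798 to 116687383) had 68 and 13 tags, and the authors' deposited table notes the TRIM32 promoter there. DTX2, a Notch pathway ubiquitin ligase, held a site with 25 and 12 tags at chromosome 7, 76485831 to 76486229. The kinase MINK1 held a site with 46 and 10 tags and a replicate 1 fold of 74.88 (chromosome 17, 4854390 to 4854745), and the epithelial keratin KRT80 a site with 51 and 10 tags (chromosome 12, 52175958 to 52176470). Sites near FRMD8, the kinase SYK and SPTLC1 lay 7.818, 44.274 and 32.032 kb outside those genes, with 36, 64 and 48 tags in replicate 1 and 13, 11 and 14 in replicate 2.

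The widest matched peaks were near EMB (796 bp, 44 and 4 tags), near STOM (595 bp, 28 and 4 tags) and the ASTN2 site (586 bp). The unmatched replicate 1 peaks with the highest fold were nearest to ANAPC1 (79.96-fold, 58 tags), DCP1A (67.48-fold, 34 tags) and LCA5 (64.36-fold, 42 tags). They lay 125.538, 13.361 and 31.299 kb outside those genes. In the separate numbering of replicate 2, the unmatched peaks of highest fold were at chromosome 10, 32258878 to 32259086 (795.37-fold, 23 tags), chromosome 11, 61158725 to 61158900 (723.07-fold, 21 tags) and chromosome X, 138934612 to 138934717 (723.07-fold, 20 tags). The chromosome X peak was 106 bp wide, little more than the modelled fragment length of 86 bp, so its 20 tags cover few positions. It may hold shifted copies of 1 fragment, which was not tested for this peak.

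Matched peaks of replicate 1 had a higher median fold than its unmatched peaks. The median fold was 19.42 in matched and 13.28 in unmatched peaks of replicate 1, a difference of 6.14 (two-sided permutation p = 1.0e-05, the smallest possible) that fell to 2.29 with 1 supporting pair. In replicate 2 the medians were 100.56 and 108.46, a difference that did not pass the threshold (permutation p = 0.0777). It did pass with all widths (-12.2, permutation p = 0.009) and with 1 supporting pair (-13.7, permutation p = 5.0e-04). Width enters here: the 729 replicate 2 peaks of 100 bp or less, of which 3 were matched, had a median fold of 144.61. Wider peaks had 90.17, so the lower matched median does not show weaker fold at matched sites of like width. Across the 205 pairs, fold correlated between the lists with Pearson's r = 0.374 and Spearman's rho = 0.333 on the log2 scale (permutation p = 1.0e-05, the smallest possible, and 2.0e-05; adjusted over 3 measures, 1.0e-05 and 2.0e-05). Without the 2 pairs farthest from the median, r was 0.339. The correlation is across peaks, which are not independent replicates. The share of replicate 1 peaks that were matched was 0.581% (Wilson interval 0.266 to 1.26) among 1033 peaks of 8 tags, 21.8% (15.9 to 29.1) among 147 peaks of 31 to 50 tags and 7.30% (4.01 to 12.9) among 137 peaks over 50 tags. Replicate 1 peaks over 100 tags, at any width, lay mostly in the widest gene-free spans (121, against 45 elsewhere on the chromosomes). The last share therefore does not show that the strongest p63 sites failed to recur.

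TP63, the gene of p63 itself, held 2 replicate 1 peaks inside its span (gene 8626, chromosome 3, 189596746 to 189897276). The stronger TP63 peak, at 189833889 to 189834334, had 38 tags (26.9 to 52.2) and a fold of 20.22 and was matched by a replicate 2 peak of 4 tags. The weaker, at 189824911 to 189825243, had 17 tags (9.90 to 27.2) and a fold of 9.81 and was not matched. Within 600 kb of TP63 the strongest peak lay 140.891 kb beyond the gene, at 190037956 to 190038381, with 48 tags (35.4 to 63.6) and a fold of 42.79. This strongest peak was not matched in replicate 2. A matched peak lay 428.866 kb beyond the gene with 31 and 7 tags, and another 286.959 kb before it with 13 and 5 tags. KDM2A, a histone demethylase gene, held no peak, and the nearest lay 36.628 kb away with 10 tags. KDM2A is named because the authors' deposited table remarks on its lack of p63.

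**Figure D2:**
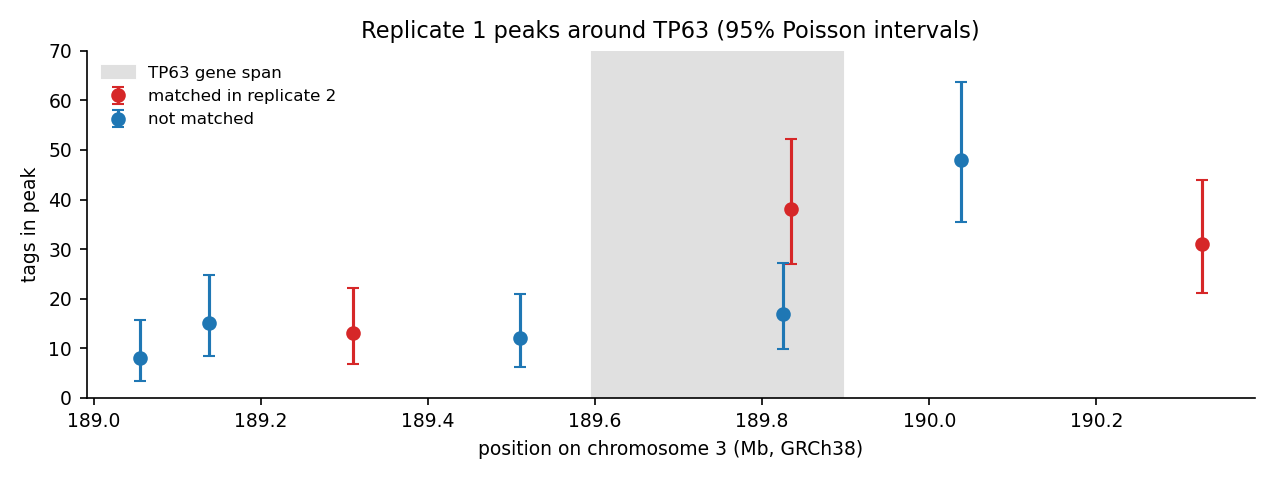
Replicate 1 peaks within 600 kb of TP63 on chromosome 3 (x axis, position in Mb, GRCh38; y axis, tags in the peak with 95% Poisson intervals), with the gene span in grey and peaks matched in replicate 2 in red. The tallest, with 48 tags, lies outside the gene, and 2 peaks lie inside it.

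Genes of basal keratinocyte adhesion, epithelial transcription factors and canonical p53 targets held replicate 1 peaks more often than random genes of like span and surroundings. Among basal adhesion and keratin genes, 13 of 33 held a peak against 3.56 in random lists (two-sided permutation test against matched random lists, p = 4.0e-04, adjusted p = 0.0028). They included the keratins KRT17 and KRT16, which share 1 peak of 8 tags (fold 20.76), the kindlin FERMT1 with 9 tags and the desmosomal plakophilin PKP3 with 11 tags. ITGA2, an integrin subunit for collagen and the 1 matched member of this list, had a peak of 59 tags. Among epithelial transcription factors, 11 of 33 held a peak against 3.13 (permutation, adjusted p = 0.0028), led by CEBPA (22 tags, fold 36.33), BHLHE40 (12 tags, fold 25.32), the retinoid receptor RXRA (25 tags, fold 20.4) and TP63. Of canonical p53 targets, 9 of 33 held a peak against 2.76 (permutation, adjusted p = 0.0084), led by the apoptosis gene BBC3 (21 tags, fold 41.52), the p53 ubiquitin ligase MDM2 (39 tags, fold 33.63), the cell cycle inhibitor CDKN1A (16 tags, fold 30.51) and GADD45A (24 tags, fold 25.13). The p53 call ended with 50 kb either side of the span, where 10 members against 5.98 gave an adjusted permutation p of 0.33. With 100 kb it was also lost, at 12 members against 9.30 (permutation, adjusted p = 0.492). The basal adhesion call ended at a score of 100 or more, where 1 member was left against 0.798 (permutation, adjusted p = 1), and no list was called from matched peaks alone.

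Of genes known from other work to be bound by p63, 7 of 33 held a peak against 3.08, which did not pass the threshold (permutation, adjusted p = 0.176). The highest ranked were FGFR2 (25 tags, fold 49.92), CDKN1A, TP63 and RIPK4 (18 tags, fold 18.19). With 50 kb either side of the span, 14 known p63-bound genes against 5.96 passed it (permutation, adjusted p = 0.0103). The list also passed with 100 kb, where 18 against 9.25 held a peak (permutation, adjusted p = 0.0112), and with the gene span alone, where 7 against 2.20 did (permutation, adjusted p = 0.0345). It passed too at a score of 100 or more, with 4 against 0.654 (permutation, adjusted p = 0.0457), and by nearest gene, with 16 against 4.69 (permutation, adjusted p = 0.0014). In 6 of 11 alternatives the known p63-bound list did not pass. Among these were a fold of 10 or more, with 7 against 2.875 (permutation, adjusted p = 0.115), and Fisher's exact test with the 10 kb window (adjusted p = 0.259). A false discovery rate limit of 1% removed no replicate 1 peak, since the highest was 0.18%. That limit, leaving out peaks over 3 kb and leaving out gene-free spans all repeated the main 7 against 3.08. They are therefore no separate failures. In this list 13 genes also belong to another list.

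The remaining lists did not pass the threshold with the 10 kb window. Epidermal differentiation genes held peaks at 4 of 33 members against 2.51, at TGM5, S100A8, ABCA12 and KRT1. AP-1 and immediate early genes had 2 of 24 against 1.19 (ATF3 and KLF6), EGF receptor family genes 2 of 20 against 2.62 (SPRED2 and ERBB4), Notch pathway genes 3 of 29 against 3.28 (MAML2, HES4 and DTX4) and cell cycle genes 3 of 30 against 2.39 (CDC25C, E2F1 and AURKA). With 100 kb either side of the span, 13 AP-1 and immediate early genes against 6.25 passed it (permutation, adjusted p = 0.0238). Among lists of other cell types, melanocyte genes had 0 of 18 against 2.31 (permutation, adjusted p = 0.424) and fibroblast genes 2 of 24 against 2.52 (COL5A2 and COL5A1). Neuronal synapse genes had 3 of 29 against 4.83 (GRIN2A, SYN3 and NLGN1), hepatocyte genes 1 of 27 against 2.13 (TAT) and blood cell genes 1 of 28 against 2.10 (CSF1R). Across all 20037 protein-coding genes, 2038 (10.2%) held a peak.

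**Figure D3:**
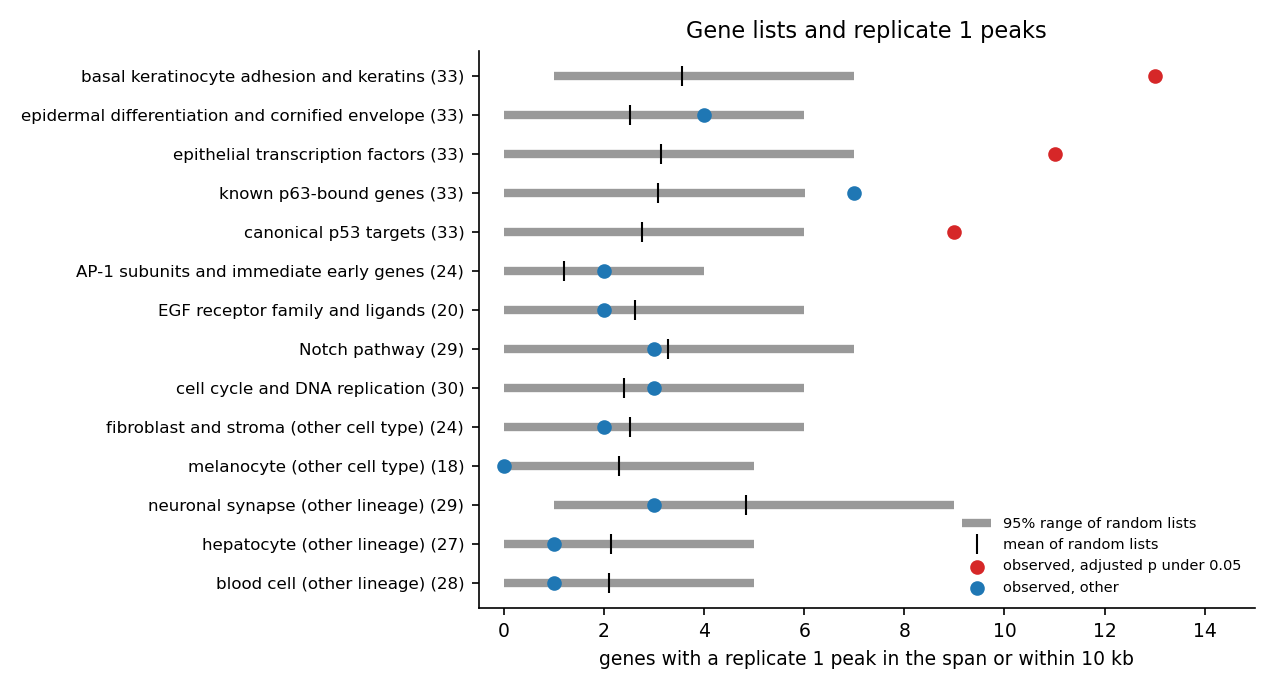
Number of genes per list with a replicate 1 peak in the span or within 10 kb (points; red, adjusted p under 0.05), with the mean (tick) and 95% range (bar) of 10000 random lists; list sizes are in brackets. The basal adhesion, epithelial factor and p53 target lists lie above their ranges at 13, 11 and 9 genes, and known p63-bound genes lie at 7.

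Ends of protein-coding genes held more replicate 1 summits than random positions did. Within 1 kb of either end lay 152 of 3994 summits (3.81%), against 2.61% of random placements (two-sided permutation p = 0.002, the smallest possible). Inside genes lay 1655 summits (41.4%), against 42.4% at random (permutation p = 0.24). Without the widest gene-free span of each chromosome the share inside genes was 49.0%, against 45.2% of random placements that also left those spans out (permutation p = 0.00664, the smallest 300 placements can give). Strand was not used, so starts and ends of genes were not told apart.

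Chromosomes 5, 9 and 8 held more replicate 1 peaks than their share of protein-coding genes, and chromosomes 18, X and 4 fewer. Chromosome 5 held 438 peaks, 2.44 times expectation (exact binomial test, two-sided, adjusted p = 3.8e-62), or 1.84 times by share of sequence length. By the same exact test chromosome 9 held 281 (1.82 times, adjusted p = 5.8e-20) and chromosome 8 held 232 (1.63 times, adjusted p = 5.0e-12). Chromosome 18 held 16 (0.299 times, exact test, adjusted p = 1.1e-08), X 67 (0.398 times, adjusted p = 1.6e-18) and chromosome 4 held 71 (0.465 times, adjusted p = 3.8e-13). In replicate 2, chromosomes 5, 8 and 9 were also above expectation, at 1.44, 1.34 and 1.60 times (exact test, adjusted p = 4.1e-06, 0.00155 and 1.1e-08). Chromosome X was again below, at 0.722 times (exact test, adjusted p = 0.00263), while chromosome 18, at 0.773 times, did not pass the threshold (exact test, adjusted p = 0.205). Chromosome 4 lay above it, at 1.67 times (exact test, adjusted p = 3.4e-10), unlike in replicate 1. Neighbouring peaks are not independent, so these p-values are too small.

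**Figure D4:**
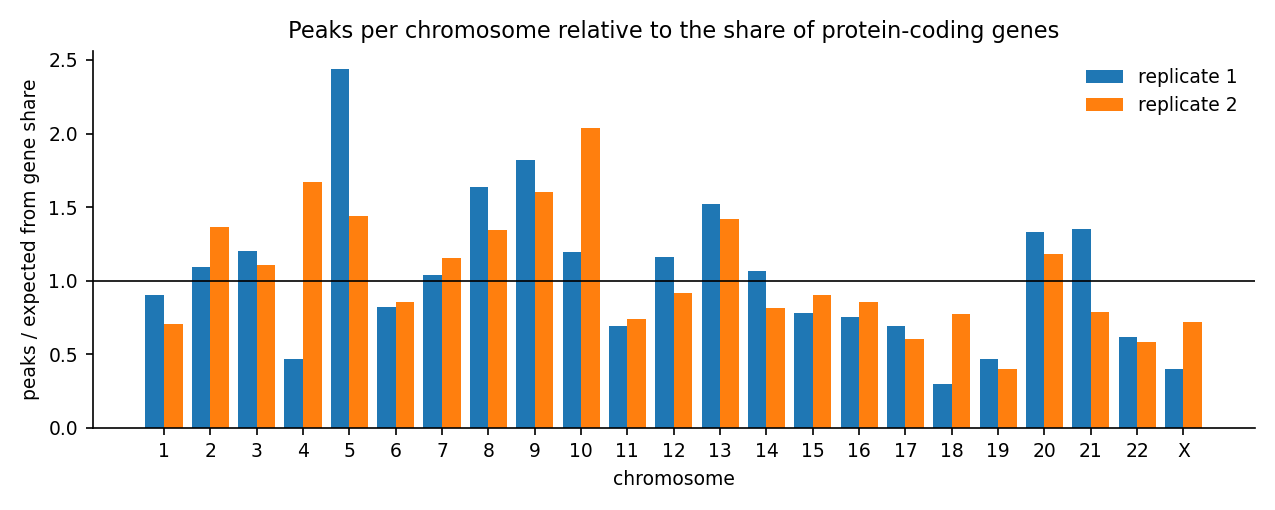
Peaks per chromosome (x axis) divided by the number expected from the share of protein-coding genes (y axis, ratio; line at 1), for replicate 1 (blue) and replicate 2 (orange), without error bars. Chromosome 5 stands highest in replicate 1 at 2.44 and chromosome 10 in replicate 2 at 2.04.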

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

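Replicate 1 held 83 peaks with 12512 tags on alternate, random or unplaced contigs, which no comparison used. They made up 8.07% of all tags in peaks at a median fold of 8.24. No explanation was tested for them.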

How the results depend on the processing

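Alternatives in the matching of peaks, the removal of gene-free spans and the widths of gene windows were chosen after seeing the data. Among results past their threshold, direction changed only for single chromosomes. Direct overlap fell to 5 peaks at 50% reciprocal overlap, 6 with summits within 100 bp and 6 at a score of 100 or more. Spacing-matched pairs numbered 25 at a score of 100 or more. With 2 supporting pairs they numbered 6, 33 and 52 in blocks of 2 Mb at tolerances of 20, 50 and 100 bp, 36 and 106 in blocks of 5 Mb at 20 and 50 bp, and 70 in blocks of 10 Mb at 20 bp. With 1 supporting pair they numbered 544 (chance mean 242.3) as in the report otherwise, 123 at 20 bp in 2 Mb, 311 and 423 at 50 and 100 bp in 5 Mb, and 400 at 50 bp in 10 Mb. Fewer pairs under narrower blocks follow from the construction. The difference in median fold between matched and unmatched replicate 2 peaks passed the threshold with all widths (-12.2) and with 1 supporting pair (-13.7). Nearly all peaks of 100 bp or less, with a median fold of 144.61 against 90.17 in wider peaks, were unmatched in the main setting. The difference was not tested among peaks of like width. The share of summits inside genes passed the threshold, above chance, at a score of 100 or more (47.8%), at a fold of 10 or more (46.9%), without gene-free spans (49.0%, where chance was 45.2%) and for matched peaks (50.7%). From matched peaks alone 0 gene lists were called, where few genes have a peak. Chromosomes called numbered 20, and 13 without replicate 1, and 11 without gene-free spans by sequence length outside them; the cause was not tested. Chromosomes 5, 8, 9 and X kept their direction and call in all alternatives, and 18 kept its direction but lost its call in replicate 2 (0.773) and in replicate 2 peaks over 100 bp wide (0.655). Of called chromosomes, by sequence length in place of gene share, the ratio changed direction on chromosomes 1 (1.13), 3 (0.983), 10 (0.994), 11 (1.02), 13 (0.681), 16 (1.08), 17 (1.47) and 19 (1.76), and without gene-free spans as well on 1 (1.07), 10 (0.991), 11 (1.11), 13 (0.778), 16 (1.16) and 17 (1.55). In replicate 2 it changed on chromosomes 4 (1.67), 12 (0.918) and 21 (0.786), and in its peaks over 100 bp wide on the same 3 (1.73, 0.881 and 0.973). Of chromosomes not called, direction changed by sequence length on 2 (0.858, now called), 7 (0.926) and 14 (0.926), without gene-free spans as well on 2 (0.955) and 7 (0.948), and on 14 in replicate 2 (0.817) and its peaks over 100 bp wide (0.707, now called); the cause was not tested. The fold correlation stayed positive and past the threshold in 8 of 8 alternatives (0.291 to 0.502), and the replicate 1 difference in fold in 4 of 4 (2.29 to 6.14). Both sets include a false discovery rate limit of 1%, which removed no peak. The highest rate was 0.18% in replicate 1 and 0.04% in replicate 2, so that alternative only repeats the main result. No paired analysis was possible because the inputs, which share replicate numbers with the IPs, have no list used here. Not run were the motif alternatives, windows around transcription starts, unions of the lists, replicate 2 alone for genes and location, and other overlap rules for shared peaks in the later comparisons, since the numberings differ; other sheets hold the same peaks. Depth limits replicate 2, where 55.0% of peaks hold 4 tags.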

Other observations

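Peaks of replicate 1 gathered in 7 of 20037 genes beyond the genome-wide rate (exact Poisson test, one-sided, Benjamini-Hochberg adjusted p under 0.05, chosen after the data were seen). Peaks were counted in the gene span or within 10 kb, without those in gene-free spans or 1 kb wide or more. SCHIP1, a cytoskeletal adaptor on chromosome 3, held 9 against 0.754 expected (exact test, adjusted p = 0.00221), and 4 of them were matched in replicate 2. The overlapping readthrough gene IQCJ-SCHIP1 also held 9. TP73, the p53 family member p73, held 4 peaks against 0.121 (exact test, adjusted p = 0.0264), with 20 tags in the tallest at chromosome 1, 3716939 to 3717192. Another of the 4 TP73 peaks, with 8 tags at 3717415 to 3717572, lay beside the tallest and was counted separately. TP73 was not tested with both counted as 1 site, so its call depends on taking them as independent. CDKN1A held 3 against 0.0361 (exact test, adjusted p = 0.0264). PDE6A and an uncharacterised gene on chromosome 20 were also among the 7 genes. No peak of TP73, CDKN1A, PDE6A or that chromosome 20 gene was matched in replicate 2. The exact test treats neighbouring peaks as independent, which they are not, so these p-values are too small. It also used the same rate for every chromosome, although chromosomes differed in peaks per base. The calls therefore do not separate a gene from its chromosome.

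The widest gene-free span of each chromosome, 6.60% of the sequence, held 613 replicate 1 peaks with 50.8% of the tags in peaks, at a median fold of 7.67 against 14.41 elsewhere. On chromosome 1, 5 peaks between 628954 and 634930 lay over mitochondrial-like pseudogenes such as MTCO1P12 and MTND2P28, with 148 to 638 tags each and a median fold of 4.71.

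The tests in the paragraphs that follow were chosen only after the results were seen, except the count of peaks per chromosome in replicate 2, which was planned. In replicate 2, 729 peaks were 100 bp wide or less, and 3 of them were matched (0.412%, Wilson interval 0.140 to 1.20), against 9.26% (8.11 to 10.5) of wider peaks. Low tag number alone would have given 59.1 matched narrow peaks (one-sided permutation p = 1.0e-04, the smallest possible), which argues against it. Of 627 narrow peaks with 4 to 7 tags, which could have covered up to 15 positions, 97.8% (Wilson interval 96.3 to 98.7) covered no more than 2 positions per tag and 54.4% no more than 1, against 19.7% and 0.587% for random positions under the same width limit (one-sided p for 2 positions = 1.0e-04, the smallest possible with 10000 draws from the exact chance of each peak). Stacks of shifted copies of 1 fragment, which keeping 1 tag per position would not remove, are a candidate explanation, with no biological one tested.

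Chromosome 5 held the most replicate 1 peaks, 140 of them in the gene-free span from 45696380 to 50396192. Without gene-free spans the ratio to expectation was still 1.96 (exact interval 1.75 to 2.19) by gene share and 1.42 by sequence length, so satellite sequence in that span could not be the whole cause. A copy number gain of chromosome 5 may contribute. In replicate 2 the ratio by gene share was 1.44 (1.25 to 1.65), and without input values per chromosome a gain cannot be told apart from other causes. No biological explanation was tested.

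Over all sites, 205 replicate 1 peaks were matched, and at equal enrichment 204.7 would hold the 4 tags needed at the depth of replicate 2. The 2 counts are unlike, because a match also needs a called replicate 2 peak and 2 supporting pairs. On simulated data the match recovered 40.1% of 299 planted pairs, so missed matches lower the matched counts. The nearness of the 2 totals is therefore no evidence of equal enrichment. Peaks of up to 30 tags were matched 163 times against 53.6 expected (exact Poisson test, one-sided, p = 2.7e-33), and peaks over 30 tags 42 times against 151.1. The excess argues against equal enrichment at the sites of up to 30 tags, if replicate 2 tags are independent molecules. The test covers counting error only, and shifted copies of 1 fragment would break that condition. No test was made of the shortfall above 30 tags, which missed matches would widen. Gene-free spans held 121 replicate 1 peaks over 100 tags, against 45 elsewhere on the chromosomes, at any width. The shortfall was not computed without those spans, so it does not show that strong p63 sites failed to recur. For the excess up to 30 tags, repeat sequence in the gene-free spans is also argued against. Of those matched peaks, 161 lay outside the spans, against 44.6 expected. The effect of the heavier duplicate removal in replicate 2 stays open, and no biological explanation was tested.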
